A study of Mus musculus with 12 samples.

How the data were processed

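Gene expression was measured by RNA sequencing of total RNA from mouse pancreatic islets of the C57BL/6 strain, before and after transplantation into the inguinal subcutaneous white adipose tissue, a fat depot under the skin of the groin. The 12 libraries formed 3 groups of 4: isolated islets, grafts taken 60 days after transplantation and grafts taken 120 days after. Per the labels' protocols, cDNA was made with a SMARTer Ultra Low Input kit, libraries were built with a NEBNext ChIP-seq kit and they were sequenced on a HiSeq instrument. The labels number the libraries of each group but do not say that they came from separate animals or islet preparations. The p-values therefore measure only the spread between these libraries, which may be partly technical.

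The deposited table held FPKM values made by the authors, fragments scaled to gene length and to the mapped fragments of the library, with 1 value per gene symbol and library. Per the submitters' processing notes, TopHat2, Cufflinks 2.1.1 and the mouse build mm9 were used. The gene annotation, the options and any scaling between libraries were not given in the sources used here, and no coordinates are reported. The deposited FPKM summed to between 396769 and 786366 per library, with no common total. Values at or near 0 needed care, because 9 genes were never between 0 and 10 FPKM yet were listed at 0 in some libraries and above 10 FPKM in others of the same group. They included the insulin genes Ins1 and Ins2 and broadly expressed genes such as Bclaf1, Hipk3, Nono and Sept7. A value of 0 in these rows can be a failed estimate, so Ins1 and Ins2 are given per library, without a mean or a fold. Ins1 still passed the filter, and its values as listed, with the 0, entered the test of the islet hormone list. Both insulin genes entered the hormone share described below as listed, zeros included.

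Read counts are not part of the table and the total depth is unknown. In the rows of microRNAs and small nucleolar RNAs, many ratios between libraries were whole multiples of a common step within 0.3%. The step gave the relative worth of 1 read, from 0.775 to 1.79 times that of isolated islet replicate 1. With it, between 29.6% and 60.6% of the compared rows were whole in the other 11 libraries, against a median of 0% over the steps tried. The step was the best-scoring one on these same rows, so this contrast is no test of it. This relative depth can be wrong by a ratio of whole numbers, so no count test was run and no counting interval is given. FPKM from such low-input, amplified libraries do not give independent molecules.

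All 23234 symbols were single rows. Of these, 13433 genes reached at least 1 FPKM in at least 4 libraries and were tested, and 9801 were not. Values were taken as log2(FPKM + 1), so that fold changes of low genes are understated, and no further scaling was applied. Each of the 3 comparisons was made with limma 3.58.1 in R 4.3.3 with statmod 1.5.0, on all 12 libraries with group as the only term, a mean-variance trend and robust variances. Tests were two-sided, with Benjamini-Hochberg adjustment over the 13433 genes and a threshold of 0.05. All adjusted p-values of genes come from this limma fit. Gene lists were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 32 lists tested. An alternative estimated the correlation within each list. Of 35 lists, 2 had fewer than 4 tested members (mammary and skin epithelium, skeletal muscle) and the sex-linked list served only as a check. The share of all FPKM held by 6 islet hormone genes was compared by exact two-sided permutation of 4 against 4 libraries, where 70 assignments give a smallest p of 0.0286. That ignores the pairing of the grafts described below.

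The groups, tests, gene lists and other settings to be tried were fixed before the data were examined. The genes named were set by a rule fixed at the same time, and fewer may be named in rank order. It took, in each comparison, the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap, leaving out unnamed gene models and short RNAs. It also took 16 islet, fat, vessel, matrix and blood cell genes whatever their result, of which 1 is not used here, and up to 4 members of each list with the smallest p. Genes outside the rule are marked as chosen after their values were seen. Both graft comparisons share the same isolated islets, so their overlap was set against 50 simulations of unchanged grafts, 50 more with paired grafts, added after the data had been seen, and against isolated islets split 2 and 2 in all 6 ways.

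The graft groups share replicate numbers with the isolated islets and with each other. Deviations from the group means, compared over all tested genes, paired the numbers of the day 60 and day 120 grafts: the correlations of same-numbered libraries ran from 0.18 to 0.442, with a mean of 0.313. Each graft matched its own number best, and 1 of the 24 possible pairings, the labelled one, reached that mean. The same check against isolated islets gave correlations from -0.0784 to 0.0199. The pairing of the grafts comes from the data, since the labels give only a number, and this was settled before fits with the replicate number as a block were compared.

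The fitting code was tested on simulated data with 200 changed genes, drawn from those with a mean log2(FPKM + 1) above 2 in isolated islets. Between 12303 and 12338 simulated genes passed the filter. Noise was independent for each gene, with the same spread in all libraries, so libraries that stand apart were not simulated. The shares below therefore check the code and do not measure the power in the real data. For day 60 against isolated islets, 47.7% of genes changed by 1 log2 unit and 95.6% of those changed by 2 were called, and 5.44% of calls were unchanged genes. The same shares were 56.1%, 97.8% and 4.43% for day 120 against isolated islets, and 59.0%, 99.0% and 4.82% for day 120 against day 60. Alternatives covered the pseudocount, the filter on low values, the scaling, the weighting of libraries, the replicate block, a fold limit and leaving out each library in turn. The filter was applied anew where a library was left out, so lists could lose members. Alternatives and tests added after the data had been seen are named in the closing section.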

Results

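The study asked how islet gene expression compares before and after transplantation into subcutaneous fat. Isolated islets, day 60 grafts and day 120 grafts were each measured in 4 libraries. Within groups, the correlation of log2(FPKM + 1) over tested genes ran from 0.904 to 0.973 in isolated islets, from 0.792 to 0.930 in day 60 grafts and from 0.929 to 0.962 in day 120 grafts. The first principal component held 55.4% of the variance and separated every isolated islet library from every graft. Isolated islet replicate 1 lay nearest to the grafts on it, at -46.0 against -91.3 to -86.1 for the other isolated islets. Graft day 60 replicate 1 lay apart on the second component, at -89.0 against -4.61 to 21.7 for the other day 60 grafts. The total depth was unknown. All errors are SD with n = 4 unless given as SE.

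Ins2 could not be compared between groups in this table, and Ins1 is given only by its values in each library. Ins2 was listed at 0 in 10 of 12 libraries and at 293150 and 316265 FPKM in isolated islet replicates 3 and 4. Ins1 was listed at 0 in graft day 60 replicate 4, at 29232 to 47890 FPKM in the other day 60 grafts, at 42761 to 71958 FPKM in isolated islets and at 70484 to 92935 FPKM in day 120 grafts. The 6 hormone genes Ins1, Ins2, Gcg, Sst, Ppy and Iapp held 39.9% ± 16.4 of all FPKM in isolated islets, 19.2% ± 5.48 in day 60 grafts and 30.2% ± 1.88 in day 120 grafts. The differences from isolated islets did not pass (exact permutation p = 0.0857 at day 60 and 0.371 at day 120), and day 120 exceeded day 60 at an exact permutation p of 0.0286, the smallest possible, or 0.125, also the smallest possible, with the grafts kept in pairs. These differences depended on Ins1 and Ins2, whose values entered the share as listed, with zeros that can be failed estimates. In isolated islets the share was 29.2% and 22.7% in replicates 1 and 2, where Ins2 was listed at 0. It was 55.9% and 52.0% in replicates 3 and 4, so the share and its p-values may rest on failed values. The other 4 hormone genes held 8.79% ± 3.06, 13.2% ± 5.06 and 12.3% ± 1.08 in that order, with differences of 4.39 percentage points for day 60 against isolated islets (exact permutation p = 0.171), 3.48 for day 120 against isolated islets (0.0857) and -0.905 for day 120 against day 60 (0.743). With Ins1 and Ins2 left out of the sum as well, these differences were 1.32 (0.657), 2.29 (0.0857) and 0.971 (0.83).

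At day 60, graft libraries held far more RNA of matrix, fat, macrophage and blood genes than isolated islets, and almost none of the digestive enzyme RNA. Chymotrypsinogen Ctrb1 fell from 8017 ± 6986 FPKM to 0.0245 ± 0.0490, and pancreatic elastase Cela2a from 7385 ± 6336 to 0.773 ± 0.456. Pancreatic amylase Amy2a5, at 4997 ± 4246 FPKM in isolated islets, was listed at 0 in all 8 grafts. The proteoglycan gene Dcn rose from 7.87 ± 1.31 to 1148 ± 1428 FPKM and the lysozyme gene Lyz2 from 7.15 ± 0.581 to 917 ± 1083. The gene of the chaperone Hspa5 fell from 2538 ± 481 to 579 ± 246 FPKM.

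In all, 5865 of 13433 genes changed at day 60 by limma at an adjusted p under 0.05, with 4211 higher and 1654 lower (71.8% higher), and 7056 had an unadjusted p under 0.05. That split depended on the scaling: 60.6% were higher with upper-quartile scaling, 44.8% with a sum without hormone and acinar genes, 45.2% with quantile normalization and 87.3% with scaling to endocrine reference genes. As deposited, the median log2 change of all tested genes was 0.27. Both groups did not overlap in 31.1% of genes, where chance gives 2.86%.

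In the fibroblast and fibrillar matrix list, 32 of 32 members rose, both over all genes and adjusted over the list alone. They included Dcn (log2 change 6.33, SE 0.569, adjusted p = 1.95e-05) and the collagen gene Col3a1 (5.19). In the adipocyte list 25 of 30 rose, or 28 adjusted over the list alone, among them Lgals12 (2.44) and the fatty acid transporter Cd36 (4.58), and the adiponectin gene Adipoq, named whatever its result, rose from 2.46 ± 0.461 to 349 ± 440 FPKM. In the macrophage list 24 of 25 rose, and the same number adjusted over the list alone, while the collagen gene Col1a1 and the leukocyte gene Ptprc rose by log2 5.09 and 2.48. The granulocyte list holds genes of neutrophils and of mast cells, so its call does not tell these apart. In it 10 of 12 rose by both adjustments, including the mast cell protease Mcpt4, listed at 0 in all isolated islets and at 19.8 ± 16.3 FPKM in day 60 grafts. Of 5 red blood cell genes, 4 rose by both adjustments, and the haemoglobin genes Beta-s, Hba-a1 and Hbb-b1 had the largest log2 rises of all named genes (7.47, 7.38 and 7.37), followed by the chemokine gene Ccl8 (7.07). All 5 lists were called higher by camera (adjusted p = 1.28e-12, 1.23e-07, 1.07e-08, 0.00266 and 0.01 in that order), yet each had an adjusted p of 0.628 with an estimated correlation. The red blood cell call was lost without isolated islet replicate 1 (adjusted p = 0.0583), while its value relative to all genes was nearly the same, 5.14 against 5.21.

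Other tissue lists were not called at day 60. The vessel gene Pecam1 did not pass (log2 0.62). Among 27 endothelial genes 14 rose and 1, the transcription factor gene Prox1, fell from 9.37 ± 1.44 to 2.1 ± 0.867 FPKM, with the same counts adjusted over the list alone (camera adjusted p = 0.105). Pericyte and smooth muscle genes had 7 higher and 1 lower of 15 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0826), basement membrane genes 4 higher of 14 (4 adjusted over the list alone, 0.114) and angiogenic factors 8 higher and 2 lower of 17 (9 and 3 adjusted over the list alone, 0.453). Of 8 T cell and NK cell genes 6 rose (6 adjusted over the list alone, 0.0826) and of 8 B cell and plasma cell genes 4 rose (5 adjusted over the list alone, 0.0552). Leaving out 1 graft at day 60 led to calls for the endothelial list (adjusted p = 0.0407 without replicate 2, 0.0280 without 3), the pericyte list (0.0418 without 2, 0.0333 without 3) and the basement membrane list (0.0208 without 2). It did so for T cell and NK cell genes (0.0146 without 3, 0.0433 without 4) and for B cell genes (0.0226 without 3, 0.0164 without 4, and 0.0356 without isolated islet replicate 4). Schwann cell genes had 5 higher and 1 lower of 13 by both all genes and adjusted over the list alone (0.508), and brown or beige adipocyte genes 1 each way of 4 by both (0.980). Of the lists too small to test, 2 of 2 mammary and skin epithelium genes and 2 of 3 skeletal muscle genes rose by both adjustments, and 0 of 4 sex-linked genes passed (0 adjusted over the list alone).

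The acinar list fell almost entirely, in 32 of 34 members both over all genes and adjusted over the list alone, and held 9.99% ± 8.23 of all FPKM in isolated islets against 0.0126% ± 0.00356 in day 60 grafts (exact permutation p = 0.0286). Of 12 duct genes 6 fell and 1 rose by both adjustments, including the keratin gene Krt8 (-3.53) and the mucin gene Muc1 (-3.26). Camera called both lists lower (adjusted p = 1.47e-45 and 6.77e-06), with an adjusted p of 0.209 for each with an estimated correlation. Relative to the median of all genes, the duct list moved from -1.37 to -0.79, -0.79, -0.89 and -0.77 without isolated islet replicates 1, 2, 3 and 4. The filter was applied anew each time, leaving 13312, 13313, 13300 and 13317 genes. The moves therefore need not come from the values of the library left out.

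Stress genes were lower in day 60 grafts. In the endoplasmic reticulum stress list 18 of 32 genes fell and 3 rose, with the same counts adjusted over the list alone. The phosphatase subunit gene Ppp1r15a fell from 116 ± 13.1 to 18.3 ± 5.51 FPKM (log2 -2.63, SE 0.191, adjusted p = 2.19e-06), the glutathione-degrading enzyme gene Chac1 by log2 -2.87 and the transcription factor gene Atf4 by log2 -1.47. Of 26 immediate early genes 7 fell and 1 rose by both adjustments, including the AP-1 gene Jund (-2.62) and the small Maf gene Maff (-2.42). Of 26 cytokine and NF-kappaB genes 12 fell and 5 rose by both adjustments, with the NF-kappaB inhibitor gene Nfkbia at -1.63, and of 15 heat shock genes 3 fell and 1 rose, with Hspa4l at -1.03. These 4 lists were called lower (adjusted p = 2.84e-08, 4.56e-05, 0.000508 and 0.00795). With an estimated correlation the adjusted p were 0.209, 0.628, 0.628 and 0.643. The heat shock call was lost without isolated islet replicate 1 (adjusted p = 0.127), where its value relative to all genes moved from -0.78 to -0.48. The immediate early list moved from -1.02 to -0.61 without that library and to -1.56 without graft day 60 replicate 1.

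Among endocrine genes at day 60, 6 of 22 islet transcription factor genes fell and 0 rose, over all genes and adjusted over the list alone. Glis3 fell by log2 -1.68 and Neurod1 by -1.02, both regulators of endocrine genes. Pdx1 (35.9 ± 20.9 against 37.8 ± 7.18 FPKM), Mafa (44.8 ± 22.7 against 65.7 ± 32.3) and Nkx6-1 (36.7 ± 22.4 against 45.1 ± 32.2) did not pass the test. Of 30 glucose sensing and secretion genes 2 rose and 3 fell (2 and 2 adjusted over the list alone), among them the calcium channel gene Cacna1c (-1.38) and the lipid receptor gene Gpr119 (1.42). Slc2a2 and Ucn3 had log2 changes of -0.21 and -0.25, neither past the threshold. Both lists were called lower (adjusted p = 0.000826 and 0.0132), with 0.628 and 0.687 as the adjusted p with an estimated correlation. The glucose sensing call was lost without graft day 60 replicate 1 (adjusted p = 0.266, value relative to all genes from -0.55 to -0.21). It was also lost without isolated islet replicate 1 (0.0670), where that value was nearly as large, -0.49. Granule genes had 2 higher and 2 lower of 20 (2 and 0 adjusted over the list alone, camera adjusted p = 0.153), with Tmem27 and the signal peptidase gene Sec11c higher by 1.39 and 1.16. The granule list was called lower without graft day 60 replicate 4 (0.0228).

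The hormone gene Iapp rose from 20125 ± 4264 to 40088 ± 9034 FPKM, whereas Gcg (10464 ± 7464 against 16704 ± 1289), Sst and Ppy (log2 -0.85 each) did not pass. All 3 passed without graft day 60 replicate 4, Gcg at -1.35 (adjusted p = 0.00885), Sst at -1.41 (0.00487) and Ppy at -1.18 (0.00875), and the islet hormone list was called lower (0.00696, value relative to all genes from -1.12 to -1.42). That list was also called without isolated islet replicate 3 (0.0471). Its member Ins1 was listed at 0 in graft day 60 replicate 4, possibly a failed estimate, and this 0 leaves the test with that library. The islet hormone list had 1 higher and 1 lower of 7 by both adjustments (camera adjusted p = 0.0817), and alpha, delta and PP cell genes 2 higher of 16, Pdyn (1.74) and Gc (1.65), by both adjustments (0.341). Of 23 genes normally kept low in beta cells, 15 rose (16 adjusted over the list alone), including Dcn, Igfbp4 (4.68) and Maf (3.15). That list was called higher (adjusted p = 7.66e-05), with an adjusted p of 0.629 with an estimated correlation. Of 13 genes linked to dedifferentiation 6 rose and 2 fell by both adjustments (camera adjusted p = 0.180, but 0.0452 or 0.0434 without isolated islet replicate 2 or 4). Neuropeptide gene Npy fell from 21.4 ± 4.37 to 1.16 ± 0.817 FPKM, while the retinaldehyde dehydrogenase gene Aldh1a3 rose from 0.975 ± 1.44 to 39.1 ± 18.0, Serpina7 from 2.34 ± 0.983 to 37.2 ± 15.6 and the peptide hormone gene Cck from 0.0793 ± 0.159 to 19 ± 14.2.

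Of 39 oxidative phosphorylation genes 18 rose by both adjustments, including Ndufa1 (1.21), and of 31 cell cycle genes 13 rose by both adjustments. Both lists were called higher (adjusted p = 0.0132 and 0.0434), with adjusted p of 0.773 and 0.771 with an estimated correlation. Without graft day 60 replicate 1 both calls were lost (adjusted p = 0.235 and 0.0689). Relative to all genes, the first list moved from 0.19 to 0.0174 without that library and to 0.36 without graft day 60 replicate 2. The second moved from 0.19 to 0.0966 without graft day 60 replicate 2 but did not shrink without replicate 1, at 0.21. Without isolated islet replicate 1 the call of the first was lost (0.0633), although its value was nearly the same, 0.18 against 0.19. The second was also lost without graft day 60 replicates 2 (0.239) or 3 (0.0573) or isolated islet replicates 2 (0.0681), 3 (0.0653) or 4 (0.0662). Its value was 0.14 without graft day 60 replicate 3 and 0.15, 0.14 and 0.18 without isolated islet replicates 2, 3 and 4. Interferon genes had 6 higher and 2 lower of 30 (5 and 1 adjusted over the list alone, 0.980), with Ifi27l2a and B2m higher by 6.35 and 3.01. Camera called that list lower without both isolated islet replicate 1 and graft day 60 replicate 1 (value relative to all genes -0.67, adjusted p = 0.000548). It did so too with array weights (-0.56, 0.0229) and gene-by-gene weights (-0.49, 0.0258). Hypoxia and glycolysis genes had 4 each way of 30 (2 and 1 adjusted over the list alone, 0.341), cholesterol synthesis genes 5 higher and 4 lower of 24 by both adjustments (0.326), and cyclins D and cell cycle inhibitors 6 higher and 3 lower of 17 by both adjustments (0.998).

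**Figure D1:**
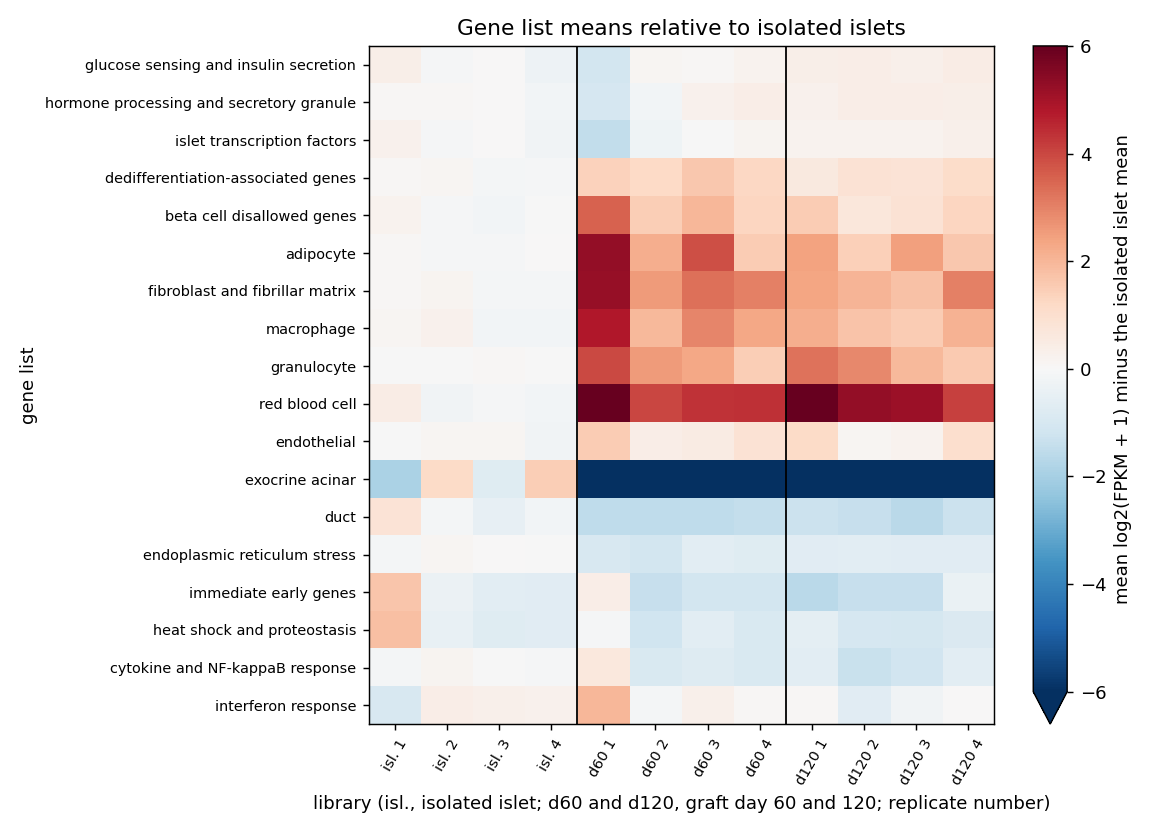
Mean log2(FPKM + 1) of 18 gene lists in each of the 12 libraries, as the difference from the mean of the 4 isolated islet libraries (colour, limited to 6 either way). Acinar genes lie below isolated islets in all 8 grafts, and graft day 60 replicate 1 has the deepest colours for matrix, fat and macrophage lists.

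At day 120, grafts again held more RNA of matrix and macrophage genes and almost no acinar RNA. Dcn stood at 264 ± 81.0 FPKM and Lyz2 at 183 ± 68.5, both higher than in isolated islets. Ctrb1 had fallen to 0.0333 ± 0.0665 FPKM and Cela2a to 0.285 ± 0.179. Hspa5 was lower at 595 ± 75.5 FPKM and Ppp1r15a at 20.8 ± 2.15. Aldh1a3 reached 40.5 ± 9.04 FPKM against 0.975 ± 1.44 in isolated islets.

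Here 4212 genes changed by limma, 3268 higher and 944 lower (77.6% higher), and 6020 had an unadjusted p under 0.05. Higher genes made up 63.8% with upper-quartile scaling, 58.5% with a sum without hormone and acinar genes, 45.6% with quantile normalization and 27.6% with endocrine reference scaling, where 410 genes were called. The last figures depended on graft day 60 replicate 1, since without it the same scaling called 3821 genes, 44.1% of them higher. The median log2 change of all tested genes was 0.30, and the groups did not overlap in 35.5% of genes, where chance gives 2.86%. The count fell to 1885, 1931 or 1839 without isolated islet replicate 2, 3 or 4 and to 2546 or 2557 without graft day 120 replicate 2 or 4.

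Fibroblast and matrix genes rose in 28 of 32 (30 adjusted over the list alone), with Col3a1 at log2 3.52 and Col1a1 at 3.56. Adipocyte genes rose in 17 of 30 (18 adjusted over the list alone), with Lgals12 at 1.97 and Cd36 at 3.22, and macrophage genes in 20 of 25 (21 adjusted over the list alone), while Ptprc did not pass (1.32). Of 12 genes on the granulocyte list, which includes mast cell genes, 9 rose, Mcpt4 reaching 8.57 ± 2.50 FPKM. All 5 red blood cell genes rose, and both counts were the same when adjusted over the list alone. These 5 lists were called higher (adjusted p = 6.26e-08, 0.00121, 3.85e-05, 0.00327 and 0.00120). With an estimated correlation the adjusted p were 0.745, 0.961, 0.812, 0.745 and 0.641. The granulocyte call was lost without isolated islet replicate 1 (adjusted p = 0.0652), where its value relative to all genes was 2.14. That was nearly unchanged, since with every library its median was 2.48, against 0.30 for all genes.

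Acinar genes fell in 33 of 34 and duct genes in 7 of 12, both also adjusted over the list alone, with Krt8 at -2.97 and Muc1 at -3.12. Both were called lower (adjusted p = 1.28e-62 and 1.54e-07), with an adjusted p of 0.0995 each with an estimated correlation. Relative to all genes, the duct list moved from -1.39 to -0.48, -0.87 and -0.92 without isolated islet replicates 1, 3 and 4, with the filter again applied anew. Stress lists were again lower. Endoplasmic reticulum stress genes fell in 12 and rose in 3 of 32 (14 and 4 adjusted over the list alone), led by Ppp1r15a (-2.42), Hspa5 (-2.08), Ddit3 (-1.90), the gene of the stress transcription factor CHOP, and Atf4 (-1.20). Immediate early genes fell in 10 of 26 and none rose (10 and 1 adjusted over the list alone), with Jund at -2.34 and Maff at -2.19. Cytokine and NF-kappaB genes fell in 14 of 26 by both adjustments, with the adhesion molecule gene Icam1 at -2.70, and heat shock genes fell in 4 and rose in 1 of 15 by both adjustments. These 4 lists had camera adjusted p of 2.50e-08, 6.05e-09, 1.03e-08 and 8.53e-05, and 0.205, 0.641, 0.494 and 0.745 as adjusted p with an estimated correlation. Without isolated islet replicate 1 the immediate early list moved from -1.67 to -0.90 and the heat shock list from -1.08 to -0.52, relative to all genes. The acinar share was 0.00889% ± 0.000990 in day 120 grafts.

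The interferon list was called lower at day 120 (adjusted p = 0.00327), with 4 higher and 4 lower of 30 by both adjustments, Irf1 at -1.07 and Ifi27l2a at 4.61. Its adjusted p was 0.961 with an estimated correlation, and its value relative to all genes moved from -0.62 to -0.94 without isolated islet replicate 1. Hypoxia and glycolysis genes had 1 higher and 2 lower of 30 by both adjustments (camera adjusted p = 0.0495, and 0.812 as adjusted p with an estimated correlation). Their median log2 change was 0.05, against 0.30 for all genes, and the call was lost without isolated islet replicate 1 (0.0652) or graft day 120 replicate 2 (0.103). Relative to all genes the value was then -0.31 and -0.23, so it stayed about as large.

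Endocrine lists were not called at day 120. Islet transcription factors had 1 higher and 1 lower of 22 (0 and 0 adjusted over the list alone, camera adjusted p = 0.477), Rfx6 at 1.42 and Glis3 at -0.89. Glucose sensing genes had 4 higher of 30 (1 adjusted over the list alone, 0.939), led by Gpr119 (1.66), and granule genes 4 higher and 1 lower of 20 (4 and 0 adjusted over the list alone, 0.573), led by Tmem27 (1.04) and Sec11c (0.92). Islet hormones had 1 higher and 2 lower of 7 by both adjustments (0.0963), with Iapp at 1.03 and Ppy at -1.08, and alpha, delta and PP cell genes 3 higher and 1 lower of 16 by both adjustments (0.365), with Pdyn at 1.91 and Gc at 1.54. Genes normally kept low in beta cells had 10 higher and 1 lower of 23 (12 and 1 adjusted over the list alone, 0.184), and dedifferentiation genes 6 higher and 2 lower of 13 by both adjustments (0.827), with Aldh1a3 at 4.59, Serpina7 at 3.53 and Npy at -3.14. Without isolated islet replicate 1, Nkx6-1 (log2 1.30, adjusted p = 0.0239, against 0.89 with all libraries), Slc2a2 (1.14, 0.0210, against 0.70) and Ucn3 (1.11, 0.0210, against 0.66) passed. The islet hormone list was called lower without graft day 120 replicate 4 (0.0347) or isolated islet replicate 3 (0.0395), and genes normally kept low in beta cells were called higher without graft day 120 replicate 2 (0.0383). Leaving out single libraries ended the calls of Rfx6 in 7 of 8 cases (log2 1.22 to 1.78, adjusted p up to 0.121), Glis3 in 5 (-1.07 to -0.80, up to 0.0740), Ppy in 7 (-1.35 to -0.89, up to 0.111) and Iapp in 2, isolated islet replicates 3 and 4 (0.95 to 1.16, up to 0.0597).

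Remaining lists were not called at day 120 either. Endothelial genes had 11 higher and 1 lower of 27 (13 and 1 adjusted over the list alone, camera adjusted p = 0.365, but 0.0338 without graft day 120 replicate 2), Prox1 again lower at -1.20. Pericyte genes had 4 higher of 15 by both adjustments (0.748), basement membrane genes 0 of 14 by both adjustments (0.827), angiogenic factors 5 higher and 2 lower of 17 (6 and 2 adjusted over the list alone, 0.827), T cell and NK cell genes 1 of 8 (0 adjusted over the list alone, 0.827) and B cell genes 2 of 8 by both adjustments (0.827). Oxidative phosphorylation genes had 5 higher of 39 (4 adjusted over the list alone, 0.705), cell cycle genes 2 higher and 1 lower of 31 (0 and 1 adjusted over the list alone, 0.474), cyclins D and inhibitors 6 higher and 2 lower of 17 (8 and 2 adjusted over the list alone, 0.957), cholesterol synthesis genes 3 of 24 (1 adjusted over the list alone, 0.827), Schwann cell genes 1 each way of 13 (1 and 0 adjusted over the list alone, 0.930) and brown or beige adipocyte genes 1 lower of 4 by both adjustments (0.521). No mammary, skin or muscle gene passed by either adjustment, and 1 of 4 sex-linked genes was lower (1 each way adjusted over the list alone).

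**Figure D2:**
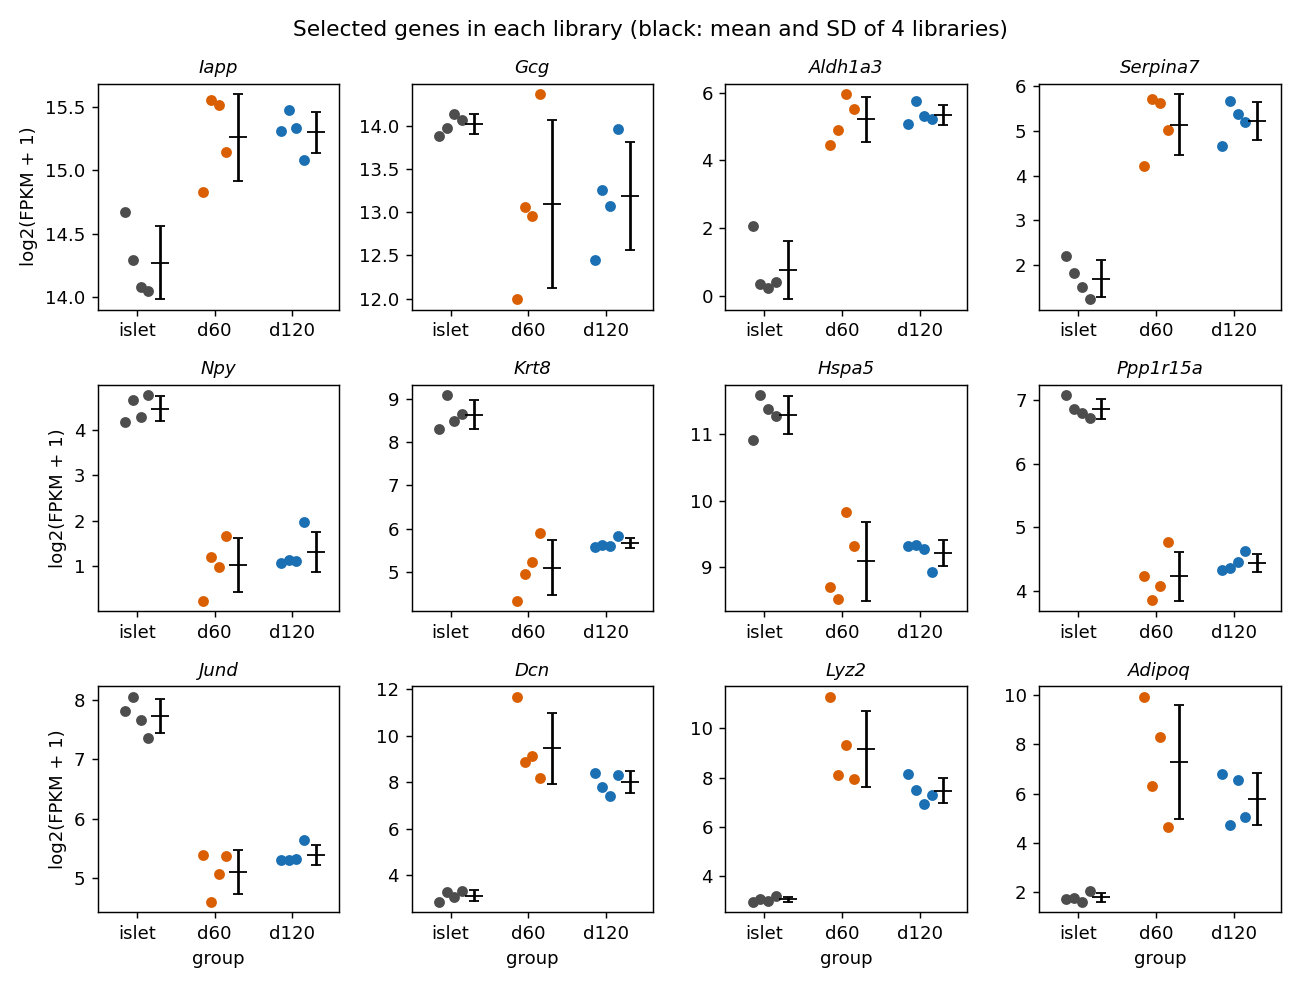
Log2(FPKM + 1) of 12 genes in each library of isolated islets (islet), day 60 grafts (d60) and day 120 grafts (d120); points are libraries and black bars the mean and SD of 4. Aldh1a3 and Serpina7 lie higher in all 8 grafts than in isolated islets, and Npy, Krt8, Hspa5, Ppp1r15a and Jund lower.

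The same genes recurred at both times. Of the genes called, 3499 were called in both graft comparisons in the same direction, 2651 higher and 848 lower, and 0 in opposite directions. Simulated unchanged grafts against the same isolated islets gave 0. With no change and independent noise for each gene almost nothing is called in either comparison, so this 0 says little about the shared islets. Independent lists of the observed sizes would share 1024 higher and 116 lower genes. With the isolated islets split 2 and 2, a mean of 402 genes (117 to 715 over 6 splits) was called in both. Independent lists of those sizes would share 73.4 higher and 13.7 lower genes. Each comparison then had only 2 isolated islet libraries, so fewer calls were to be had. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.900 against 0.501 in the simulations, and their covariance was 0.892 against 0.0567, a difference of 0.836. Those simulations took the grafts as independent, and left out libraries that stand apart over many genes. With the pairing of the grafts simulated too, r was 0.656, the covariance 0.0743 and the shared genes 0.02 on average. In the real data with the isolated islets split 2 and 2, which leaves no shared islets, r was 0.818 on average (0.772 to 0.856). The covariance was then 0.842, little below that with shared islets.

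**Figure D3:**
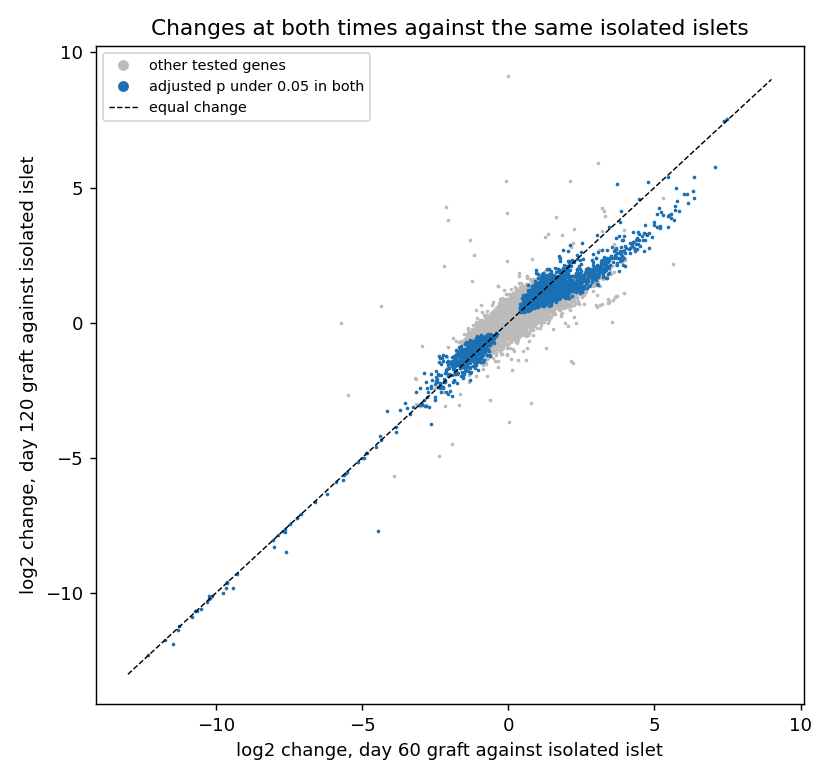
Log2 change of each tested gene against isolated islets at day 60 (horizontal axis) and day 120 (vertical axis); blue points are the 3499 genes called in both, and the dashed line marks equal change. Both axes use the same isolated islets, which gave a correlation of 0.501 in the simulations of unchanged grafts, or 0.656 with paired grafts.

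Between day 60 and day 120 grafts, few single genes differed in the fit without weights of the libraries. With array weights 2874 genes were called by the planned estimator, which did not converge, and 459 with gene-by-gene weights. Islet transcription factor and secretion lists were called higher at day 120, and several matrix, fat and immune lists lower, with a preset correlation. With an estimated correlation 0 lists were called (adjusted p = 0.381 to 0.547 for the lists called before). Pdx1 stood at 64.0 ± 8.92 against 35.9 ± 20.9 FPKM and Mafa at 109 ± 71.2 against 44.8 ± 22.7, both with an adjusted p of 0.490. Dcn stood at 264 ± 81.0 against 1148 ± 1428 FPKM, with 3284 in graft day 60 replicate 1 and 293 to 555 in the other day 60 grafts. Aldh1a3 had nearly equal levels, 40.5 ± 9.04 and 39.1 ± 18.0 FPKM (log2 difference 0.14, SE 0.404).

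By limma 2 genes differed, 1 in each direction, while 1356 had an unadjusted p under 0.05, and the groups did not overlap in 4.29% of genes, where chance gives 2.86%. Both were outside the rule and named after their values were seen. The microRNA gene Mir344g was listed at 0 in the other 8 libraries and at 561 ± 45.4 FPKM in day 120 grafts. Those 4 values differed by 21.7% but by 0.0754% once divided by the relative worth of 1 read, which can itself be wrong by a ratio of whole numbers. An equal number of reads in each library would give this, but that number is unknown, so the size of the difference is uncertain. Of 19 short RNA rows above 0 in exactly 4 libraries, 1 had all 4 in the same group. The gene model Gm9781 stood at 4.05 ± 1.06 FPKM in day 60 grafts and 0.00425 ± 0.00320 in day 120 grafts. Each gene reached 1 FPKM in only 4 libraries, so leaving out any 1 of those took it out of testing. Without any single library of day 60 replicates 1 to 3 or of day 120, 1 gene was called, and without graft day 60 replicate 4, 20 were.

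No member of any list passed over all genes. Camera called 4 lists higher at day 120. Islet transcription factors had a median log2 difference of 0.61 (adjusted p = 1.47e-07), with Glis3 at 0.79 and Tshz1 at 0.59, and glucose sensing genes 0.62 (8.87e-07), with Trpm5 at 0.97 and Glp1r at 1.17. Granule genes had 0.56 (4.36e-05), with Pcsk1n at 1.02, and endoplasmic reticulum stress genes 0.24 (0.0101), with Chac1 at 1.00. With an estimated correlation the adjusted p were 0.381, 0.381, 0.455 and 0.455. Adjusted over the list alone, 0 members of these lists passed.

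Camera called 13 lists lower at day 120. These were fibroblast and matrix (median log2 difference -1.25, adjusted p = 8.48e-17, Thy1 -1.14 and Col3a1 -1.66), macrophage (-1.14, 1.33e-12, Trem2 -1.54), adipocyte (-1.33, 2.53e-11, Dgat1 -0.78) and genes normally kept low in beta cells (-1.02, 3.36e-12, Maf -1.12). With an estimated correlation the adjusted p were 0.381, 0.381, 0.451 and 0.381, and 0 members passed adjusted over the list alone. T cell and NK cell genes (-1.11, 0.000314, Cd4 -1.13) had 3 of 8 lower adjusted over the list alone, B cell genes (-0.92, 0.000309) 1 of 8 and dedifferentiation genes (-0.22, 0.0142, Cck -1.88 and Fabp5 -1.72) 3 of 13, each with an adjusted p of 0.381 with an estimated correlation. Interferon (-0.74, 1.44e-08), cell cycle (-0.35, 2.06e-09), basement membrane (-0.62, 0.000127) and oxidative phosphorylation (-0.32, 1.52e-05) genes were also lower, with adjusted p of 0.452, 0.381, 0.452 and 0.547 with an estimated correlation. So were cytokine and NF-kappaB (-0.46, 0.00206) and pericyte genes (-0.34, 0.00631), each with an adjusted p of 0.544 with an estimated correlation. In these 6 lists 0 members passed adjusted over the list alone.

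Single libraries decided several of these list calls. Without graft day 60 replicate 1 the cytokine (adjusted p = 0.499), oxidative phosphorylation (0.138) and pericyte (0.101) calls were lost. The endoplasmic reticulum stress call was lost without graft day 60 replicate 2 (0.130), the dedifferentiation call without graft day 60 replicate 4 (0.0747), although its value relative to all genes did not shrink (-0.27 against -0.25), and the pericyte call also without graft day 60 replicate 4 (0.0924) or graft day 120 replicate 2 (0.177). Relative to the median of all genes, leaving out graft day 60 replicate 1 moved the difference of islet transcription factors from 0.58 to 0.21, glucose sensing from 0.59 to 0.22, granule genes from 0.53 to 0.21 and genes normally kept low in beta cells from -1.06 to -0.52. It moved adipocyte genes from -1.36 to -0.57, fibroblast from -1.28 to -0.66, macrophage from -1.17 to -0.50, basement membrane from -0.65 to -0.23 and interferon genes from -0.78 to -0.29. Without graft day 60 replicate 2, T cell and NK cell genes moved from -1.14 to -0.39. The other lists tested were not called: islet hormones (median log2 difference 0.04, camera adjusted p = 0.645), alpha, delta and PP cell (0.13, 0.963), brown or beige adipocyte (-0.45, 0.0788), acinar (0.00, 0.524), duct (0.16, 0.524), endothelial (-0.18, 0.118), angiogenic factors (-0.13, 0.370), granulocyte (-0.40, 0.201), immediate early (-0.42, 0.118), hypoxia and glycolysis (-0.13, 0.121), heat shock (-0.05, 0.317), cyclins D and inhibitors (-0.04, 0.870), cholesterol synthesis (0.09, 0.118), Schwann cell (-0.08, 0.118) and red blood cell (0.09, 0.524). Several were called with 1 library left out. For graft day 60 replicate 1 these were red blood cell (0.00106, value relative to all genes from 0.0588 to 0.99), cholesterol synthesis (0.0153) and Schwann cell (0.0228), without replicate 2 endothelial (0.0143), hypoxia and glycolysis (0.0104) and immediate early (0.0317). Without replicate 3 these were endothelial (0.00885), immediate early (0.0254), cholesterol synthesis (0.0339) and Schwann cell (0.00885). Without replicate 4 these were granulocyte (0.00766) and islet hormones (0.0312), whose member Ins1 was listed at 0 in that library. Without graft day 120 replicate 1 these were endothelial (0.00105) and Schwann cell (0.0188), without replicate 3 brown or beige adipocyte (0.0228), and without replicate 4 endothelial (0.0131), immediate early (0.00790) and cholesterol synthesis (0.0382). Of their members, 1 of the cyclins D and inhibitors list was higher and 0 others passed adjusted over the list alone. Of the lists too small to test, 2 of 2 mammary and skin epithelium genes were lower adjusted over the list alone (median log2 difference -1.04), and 0 of 3 skeletal muscle and 0 of 4 sex-linked genes passed.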

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

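As lists under a preset correlation, several matrix, fat and immune lists had lower medians and 3 islet lists higher medians at day 120 than at day 60, and 4 stress lists were lower in both grafts than in isolated islets. No member passed over all genes between the times. With an estimated correlation no such list was called (adjusted p = 0.381 to 0.547 between the times, 0.209 to 0.643 for stress lists at day 60 and 0.205 to 0.745 at day 120). The tests of host RNA, acinar RNA, isolation stress and graft day 60 replicate 1 below were chosen after these results were seen, and the criteria for host RNA and for that library were rewritten once values had been seen; the counts over other splits of the libraries were planned.

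In the endoplasmic reticulum stress list, 18 of 32 genes were lower and 3 higher at day 60, and 12 lower and 3 higher at day 120, with Ppp1r15a and Hspa5 lower at both. With libraries scaled to endocrine reference genes, the median log2 change at day 120 was -0.87 against -0.53 before (exact permutation p of the list means = 0.0286). That scaling also moved the median of all genes from 0.30 to 0.02, so the larger size is not particular to this list. Relative to the endocrine reference genes the list was still lower, which argues against dilution by host RNA as the only cause at that time. At day 60 the median of the list was -0.41 against -0.74 before (exact permutation p = 0.143), while that of all genes moved from 0.27 to 0.56, so dilution stays open there. Acinar RNA in the isolated islet libraries may account for part: the line over those libraries left 43.3% of the excess at an acinar share of 0, with -6.17% to 77.0% when each was left out, which decides nothing. Stress of islet isolation may also be part, since the immediate early list had a median of -1.36 and the heat shock list -0.77 at day 120. Isolated islet replicate 1 carries much of both: relative to all genes they moved from -1.67 to -0.90 and from -1.08 to -0.52 without it. Without islets left in place this cannot be told apart from an effect of transplantation.

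Between day 60 and day 120, 17 lists were called with the preset correlation and 0 with an estimated one (adjusted p = 0.381 to 0.547). By the means of each library, 4 of the 17 lists differed (exact permutation p = 0.0286) when the pairing of the grafts was ignored, while permutation within the 4 pairs cannot give a p under 0.125. Without graft day 60 replicate 1, 3 lists differed (islet transcription factors, glucose sensing and cell cycle), again without the pairing. In 7 lists (islet transcription factors, glucose sensing, genes normally kept low in beta cells, dedifferentiation, macrophage, interferon and cell cycle) the difference had the same sign in all 4 pairs. Those signs do not come from that library alone, but what it accounts for in the size of the differences and in the other lists stays open. Scaled to endocrine reference genes, the median log2 difference of islet transcription factors was 0.0557 against 0.61 before, but that scaling moved the median of all genes from 0.03 to -0.55 and holds endocrine genes near 0, so it decides nothing about a smaller share of host RNA. The red blood cell list, at 0.09, did not fall with the adipocyte, fibroblast and macrophage lists, which goes against such a share. Its value relative to all genes ran from -0.70 to 0.99 with single libraries left out, so this stays open, as does a change within the islet cells, which was not tested.

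As a list, genes normally kept low in beta cells, such as Dcn and Igfbp4, were called higher in day 60 grafts but not with an estimated correlation (adjusted p = 0.629), nor at day 120 (0.184). Over the 8 grafts, the 16 members on no other list followed the fibroblast list (Pearson r = 0.951, exact permutation p = 0.00246, Spearman rho = 0.738, exact permutation p = 0.0458), and 7 members are on other lists. These permutations ignore the 2 times and the pairing of the grafts, so their p-values may be too small. Without the 2 grafts farthest out r was 0.708 (exact permutation p = 0.101), so too few samples are left to tell whether the relation holds without them. Host cell RNA may be the source without being shown to be. Of the 32 fibroblast genes 18 reached 1 FPKM in isolated islets and 2 are on other lists. A change within beta cells was not tested.

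For day 60 against isolated islets, 1 of 35 splits of the 8 libraries, the real one, gave as many as 5865 genes, and the highest other gave 1885, a count that points to a structure of the samples. For day 120 against isolated islets it was 1 of 35 with 4212 genes and 3 at most otherwise. A share of 1 in 35 is the smallest these splits can give, which speaks against chance for these gene counts without excluding it. The splits also take the libraries as separate samples, which the labels do not say. For day 120 against day 60 it was 1 of 35 with 2 genes and 1 at most otherwise, but the numbers pair the grafts, and the 8 splits that part all 4 pairs are too few for a share under 0.05. The numbers of lists called did not stand out from those of other splits: 19 of 35 splits gave as many as the real 16 at day 60 (highest other 23), 15 of 35 as many as 13 at day 120 (highest other 18) and 21 of 35 as many as 17 between the times (highest other 23). Among those 8 splits, the real one gave 2 genes and the others at most 1, and 4 of 8 gave as many lists, the others ranging from 10 to 20.

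The differences between the times were, as median log2, 0.61 for islet transcription factors, 0.62 for glucose sensing, 0.56 for granule and 0.24 for endoplasmic reticulum stress genes. They were -1.02 for genes normally kept low in beta cells, -0.22 for dedifferentiation, -1.33 for adipocyte, -0.34 for pericyte, -1.25 for fibroblast, -0.62 for basement membrane and -1.14 for macrophage genes. They were -1.11 for T cell and NK cell, -0.92 for B cell, -0.46 for cytokine and NF-kappaB, -0.74 for interferon, -0.32 for oxidative phosphorylation and -0.35 for cell cycle genes. Graft day 60 replicate 1 carries much of most of these. Relative to all genes and without it, islet transcription factors moved from 0.58 to 0.21, glucose sensing from 0.59 to 0.22, granule genes from 0.53 to 0.21, genes normally kept low in beta cells from -1.06 to -0.52 and adipocyte genes from -1.36 to -0.57. Fibroblast genes moved from -1.28 to -0.66, macrophage from -1.17 to -0.50, basement membrane from -0.65 to -0.23, interferon from -0.78 to -0.29, pericyte from -0.37 to -0.17, cytokine from -0.49 to -0.16 and oxidative phosphorylation genes from -0.36 to -0.0624. Without graft day 60 replicate 2, T cell and NK cell genes moved from -1.14 to -0.39, dedifferentiation from -0.25 to -0.16 and endoplasmic reticulum stress genes from 0.21 to 0.12. Without graft day 60 replicate 3, pericyte genes moved to -0.61 and B cell genes from -0.95 to -1.44, without replicate 4 adipocyte genes to -2.05, and without graft day 120 replicates 2 and 4 pericyte genes to -0.19 and -0.61. Among genes, Gm9781 differed by log2 -2.30 and Mir344g by 9.13, and the hormone share by 11 percentage points, against -0.905 without Ins1 and Ins2 and 0.971 with these also out of the sum.

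Single libraries far from the other 3 of their group were found in 54 of 339 groups of values tested, or 15.9%. Chance gives about 1 in 20 for normally distributed values, which FPKM need not be. A group with 1 value above 0 and the others at 0, such as Cck in isolated islets, is always flagged. The share is therefore not a measured excess over chance. Of these, 42 were among 240 gene groups on the FPKM scale, and 21 of the 240 stood apart on the log2 scale. Isolated islet replicate 1 held 16 and graft day 60 replicate 1 held 15.

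In graft day 60 replicate 1, the list mean of log2(FPKM + 1) stood apart for glucose sensing and insulin secretion at 3.55 (others 4.70 to 4.85), immediate early genes at 4.53 (others 2.71 to 3.00), cytokine and NF-kappaB response at 3.89 (others 2.32 to 2.45) and red blood cell at 8.91 (others 5.28 to 5.66). Graft day 60 replicate 1 had Beta-s at 10524 (others 644 to 1058), Hba-a1 at 11332 (others 755 to 1035), Hbb-b1 at 6596 (others 422 to 632) and Ccl8 at 1289 (others 20.7 to 188) FPKM. The same library also had Dcn at 3284 (others 293 to 555), Igfbp4 at 402 (others 57.8 to 110), Maf at 25.6 (others 5.84 to 9.07) and Trem2 at 63.8 (others 8.08 to 16.5) FPKM. That library further had Irf1 at 30.1 (others 22.1 to 23.3), H2-Aa at 957 (others 143 to 278) and H2-Ab1 at 431 (others 99.3 to 150) FPKM. Both H2 genes were chosen after their values were seen.

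In isolated islet replicate 1, the list mean of log2(FPKM + 1) stood apart for immediate early genes at 5.78 (others 3.42 to 3.74), interferon response at 2.51 (others 3.72 to 3.84) and heat shock and proteostasis at 7.10 (others 4.58 to 4.87). Isolated islet replicate 1 had Beta-s at 15.5 (others 5.95 to 6.66), Hbb-b1 at 10.9 (others 3.79 to 3.98), Nkx6-1 at 93.2 (others 25.8 to 30.9) and Slc2a2 at 174 (others 41.4 to 61.1) FPKM. The same library also had Ucn3 at 361 (others 93.9 to 121), Rfx6 at 33.0 (others 9.69 to 12.8), G6pc2 at 1133 (others 156 to 265) and Aldh1a3 at 3.14 (others 0.18 to 0.32) FPKM. That library further had Lgals12 at 5.98 (others 2.09 to 2.59), Maff at 40.1 (others 16.7 to 20.5), Atf4 at 278 (others 312 to 317) and Ddit3 at 159 (others 66.5 to 79.8) FPKM. That library further had Epcam, chosen after its values were seen, at 84.7 (others 123 to 125) FPKM.

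Graft day 120 replicate 4 had Ctrb1 at 0.133 (others all 0), Col1a1 at 127 (others 21.1 to 29.6), Npy at 2.94 (others 1.10 to 1.19) and Col3a1 at 139 (others 37.6 to 50.8) FPKM. The same library also had Jund at 48.9 (others 38.5 to 38.9), Hspa5 at 483 (others 618 to 644) and Mt2, chosen after its values were seen, at 55.2 (others 26.3 to 27.9) FPKM.

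In graft day 120 replicate 1, the list mean of log2(FPKM + 1) stood apart for hormone processing and secretory granule at 8.23 (others 8.33 to 8.35). Graft day 120 replicate 1 had Beta-s at 7978 (others 687 to 1394), Hba-a1 at 8392 (others 775 to 1429), Hbb-b1 at 5190 (others 443 to 906) and Mafa at 215 (others 63.8 to 79.0) FPKM.

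In isolated islet replicate 4, the list mean of log2(FPKM + 1) stood apart for hormone processing and secretory granule at 7.78 (others 8.0 to 8.03), basement membrane at 2.22 (others 2.51 to 2.56) and cyclins D, cell cycle inhibitors and senescence at 3.32 (others 3.44 to 3.46). Isolated islet replicate 4 had Gm9781 at 0.003 (others all 0.001) FPKM.

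In graft day 120 replicate 2, the list mean of log2(FPKM + 1) stood apart for cholesterol synthesis at 3.95 (others 3.60 to 3.65). Graft day 120 replicate 3 had Gm9781 at 0.009 (others 0.002 to 0.003) FPKM. Graft day 60 replicate 3 had Gm9781 at 2.47 (others 4.48 to 4.73) FPKM. Graft day 60 replicate 4 had Ctrb1 at 0.098 (others all 0) and Ppy at 7536 (others 2654 to 3338) FPKM. Isolated islet replicate 2 had Cck at 0.317 (others all 0) FPKM. Isolated islet replicate 3 had Ccl8 at 0.312 (others all 0) FPKM.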

How the results depend on the processing

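The alternatives without short RNAs, with failed zeros set missing, without both libraries that stand apart, with only the 8 graft libraries, with 4 hormones and each sum, with gene-by-gene weights and with endocrine scaling of 11 libraries were chosen after seeing the data. Gene counts are given for day 60 and day 120 against isolated islets and for day 120 against day 60, where 5865, 4212 and 2 were called. A mean of at least 5 FPKM, which tests fewer genes, gave 3699, 2666 and 1, and a fold of at least 2 gave 2981 and 1932. No filter on low values gave 4 in the last comparison, and leaving out short RNAs 1. Endocrine reference scaling gave 3542 and 410 (87.3% and 27.6% higher), but with 11 libraries, without graft day 60 replicate 1, 4949, 3821 and 1 (70.5% and 44.1% higher in the first 2). Array weights by the planned estimator, which did not converge and gave graft day 60 replicate 3 a weight of 15.5, gave 10359, 8943 and 2874, and gene-by-gene weights 9356, 8853 and 459. Without both libraries that stand apart, day 120 had 7437 genes, the last comparison 1 and both graft comparisons 6599 in common, against 3499, and splitting the isolated islets 2 and 2 gave a mean of 402. The cause of these shifts, other than fewer genes or libraries, was not tested. An estimated correlation gave 0 lists in each comparison, and array weights 11 lists in the last. Endocrine scaling moved the median of all genes to 0.56, 0.02 and -0.55, from 0.27, 0.30 and 0.03.

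Leaving out each library gave 4074 to 6861, 1839 to 5516 and 1 to 20 genes and 12 to 20, 11 to 14 and 16 to 21 lists. The hormone share includes Ins1 and Ins2 as listed, with zeros that can be failed estimates. Its difference ran from -26.5 to -15.5, from -15.5 to -4.43 and from 8.49 to 12.4 percentage points. At day 60 it passed at -26.5 without isolated islet replicate 2 (exact permutation p = 0.0286) and at -25.1 without acinar genes in the sum, and Gcg, Sst, Ppy and Iapp alone turned the 3 differences to 4.39, 3.48 and -0.905 (exact permutation p = 0.171, 0.0857 and 0.743). With Ins1 and Ins2 out of the sum too, they were 1.32, 2.29 and 0.971 (0.657, 0.0857 and 0.83).

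Reversed at day 60 were Pdx1 (0.56), Nkx6-1 (0.46), Glp1r (0.76) and the interferon list (-0.56) with array weights, Glp1r (0.67) and the interferon list (-0.49) with gene-by-gene weights, and Glp1r (0.56) and the interferon list (-0.67) without both libraries that stand apart. Between day 60 and day 120, Hspa5 reversed to -0.52 with array weights, the acinar list to 0.55 with endocrine scaling, and with 11 libraries the acinar (0.24), granulocyte (0.17), immediate early (0.0308) and cytokine lists (-0.12). A result counts as reversed where its direction turned and either fit called it. None of these genes, and no list among these but the cytokine list, was called in the main fit. The cytokine list was not called in the alternative (camera adjusted p = 0.406). List values here are medians relative to that of all genes, while direction is that of camera, which turned for the cytokine list at a value still below 0. The cause was not tested.

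With the replicate number as a block, 5804, 4254 and 2 genes and 19, 13 and 17 lists were called, and 3 genes and 19 lists with only the 8 graft libraries; no count moved by over 1.5 times. Taking the highest row per symbol was not run, since no symbol was repeated. Of the values of named genes over all alternatives, 1900, 1779 and 2012 kept their side of the threshold, 29, 154 and 0 lost their call and 41, 42 and 50 gained one. Direction was compared only where either fit called the gene, so those that stayed uncalled may have changed sign. The total depth is unknown, so what it limits could not be computed.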

Other observations

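Cldn4, Mt1 and Mt2 were lower and H2-Aa higher in both grafts than in isolated islets. The tight junction gene Cldn4, chosen after its values were seen, fell from 249 ± 117 FPKM in isolated islets to 13.2 ± 7.91 at day 60 and 22.9 ± 6.25 at day 120 (log2 -4.15 and -3.26). The metallothionein genes Mt1 and Mt2, also chosen after their values were seen, fell by log2 -2.51 and -2.81 at day 60 and by -2.87 and -3.09 at day 120. Antigen presentation gene H2-Aa, chosen likewise, rose from 43.3 ± 1.62 FPKM to 412 ± 368 at day 60 and 139 ± 30.1 at day 120. All were past the limma threshold, and no explanation of them was tested.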
